A study of Mus musculus with 24 samples.

How the data were processed

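Messenger RNA levels were measured by sequencing on an Illumina HiSeq instrument in stromal cells taken from embryonic mouse kidneys by fluorescence-activated sorting of cells marked by a FoxD1Cre-eGFP transgene. The labels give 24 libraries in 8 groups of 3: cells with deficient beta-catenin (SD) on a C57BL/6 background, cells with stabilised beta-catenin (SO) on a CD1 background, and wild-type cells of each background, all at embryonic day (E) 12.5 and E13.5. Every column of values was mapped to a library by its label, and 0 columns stayed unmapped. The series record speaks of 3 kidneys for each genotype, and the labels do not say whether libraries of a group came from separate kidneys, animals or litters, so each p measures the spread between these libraries. Sex-linked transcripts, given at the end, show RNA of both sexes in every library but SD E12.5 replicate 3, so most libraries may be pools of embryos. Strain and colony go with the line, and the alleles used to delete or stabilise beta-catenin are not given in the sources used here.

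The deposited values are log2 CPM (counts per mega-read), after TMM scaling of the library sizes and with 0.5 added to each count, the scale that limma's voom uses. The authors' processing notes name HISAT2, HTSeq, limma and the mm10 build of the genome without versions. Neither a filter on low genes nor the strand of counting is given in the sources used here. Whole reads were recovered from the values of each library, and 100% of values lay within 0.1 of a whole number. Library totals ran from 6.18 to 21.2 M reads (M, mega) over the 13803 genes of the file. Intervals and floors given with read counts cover counting error only, since reads without molecular identifiers are not independent molecules.

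The deposited values were fitted in R 4.3.3 with limma 3.58.1, using 8 group means over 24 libraries, empirical Bayes moderation with a mean-variance trend, 16 residual degrees of freedom and 6.43 prior degrees of freedom. A gene was tested when at least 3 of the 24 libraries exceeded a log2 CPM of 0, which removed no gene. It was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested, with no minimum fold change. All tests were 2-sided. There were 11 contrasts: SD and SO against wild-type of the same strain at each stage and as the mean of the stages, the difference of each effect between stages, E13.5 against E12.5 in each wild-type strain, and C57BL/6 against CD1 wild-type. Overlaps of called genes between contrasts were tested with Fisher's exact test across genes, which are not independent replicates.

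There were 29 fixed gene lists, of which 28 were tested, because 0 of the 13 mitochondrial transcripts were in the file. Lists were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists within a contrast, and again with a correlation estimated for each list. Member counts are given over all genes and adjusted over the list alone. Camera compares the members with all other genes, so its direction can differ from the sign of a list's mean or median. The rule for naming genes took, in each genotype contrast within a stage, the 6 largest rises and the 6 largest falls among called genes whose 3 mutant libraries all lay beyond the 3 wild-type libraries, whose mean log2 CPM was above 0 and whose symbol is a given name. It took 5 each way in the other contrasts, the 4 smallest p of each called list and of the lists of the study's question in the means of stages, 6 genes each way that moved oppositely in SD and SO, and Ctnnb1, Foxd1, Axin2, Lef1 and Nkd1 in every genotype contrast. The 20 symbols that spreadsheet software had turned into dates were left out of the naming. The contrasts, lists, tests, naming rule and first set of alternatives were chosen before the data were examined.

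Genes with 1 to 3 reads in a group are given as a ratio of summed reads with an exact 95% counting interval, and genes with no read against a floor of 3 reads over the group. Fitted fold changes of genes with few reads depend on the 0.5 added to each count. Positions are from GENCODE M21 on GRCm38 (mm10), to which 13657 of the 13803 symbols (98.9%) and 158 of the 160 named genes matched. Transcripts of these 158 genes were searched with BLAST 2.17.0 for other loci with at least 95% identity over at least 200 nucleotides. Such a match, called near-identical below, can cover only a part of the transcript. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

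The fit was tested on simulated data with the depth of these libraries and the spread of each gene, taken as equal in all libraries. It recovered 68.3% of 2-fold changes in SD against wild-type at E12.5, 68.2% in SO against wild-type at E13.5 and 78.8% in the SD mean of stages. For 4-fold changes the shares were 80.3%, 80.3% and 92.2%. False calls made up 2.88%, 1.63% and 3.18% of the calls, and 0 of 168 tests of unchanged lists by camera were called. Genes were simulated independently of each other, so the list result cannot show whether the preset correlation of 0.01 is high enough for these data. The real libraries differed in spread, with limma's array weights from 0.389 to 2.22. The shares of recovered and of false calls therefore hold for the simulated setting only. Replicate numbers were not taken to pair libraries: the deviations of equally numbered libraries from their group means correlated with r from -0.36 to 0.28. The values were 0.2, 0.07 and 0.28 between SD and wild-type at E12.5, where 3 of 3 SD libraries matched best with their own number, and 1 of the 3 was not over 0.1. The alternatives tried were median centring, quantile normalization, no filter, a stricter filter at a log2 CPM of 2, a pseudocount of 1, no variance trend, array weights, voom weights on the recovered reads, a block for the replicate number, fits on the 12 libraries of a line or on 2 groups only, and leaving out each library in turn. Added after the data were seen were fits with the means of the macrophage, endothelial and erythroid lists as covariates, fits with the mean of the Y-linked genes as a covariate, fits without the 2 libraries highest in the liver transcript Alb, list tests on the stage differences, and 20 random thinnings of all libraries to 6.18 M reads.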

Results

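Stromal cells give rise to the supporting tissue of the kidney and signal to the nephron progenitors beside them, and beta-catenin carries the canonical Wnt signal in these cells. The 24 libraries formed 8 groups of 3, and each mutant had wild-type libraries of its own strain and stage. Mean depth was 10.2 M reads in SD at E12.5, 7.34 in SD at E13.5, 6.43 in SO at E12.5 and 15.4 in SO at E13.5. The wild-type means were 11.4 and 8.34 M reads in C57BL/6 and 9.71 and 10.1 in CD1, at E12.5 and E13.5. Pairs of libraries within a group correlated with r between 0.927 and 0.978 across genes. On the first principal component, with 30.4% of the variance, the 6 SD libraries lay between -74.6 and -35.4, the 12 wild-type libraries between -32.9 and 36.7, and the 6 SO libraries between 43.2 and 67.4. Wild-type libraries of C57BL/6 lay between -32.9 and 17.5 and those of CD1 between -15.2 and 36.7. Strain goes with the line, so this order cannot be put down to genotype alone.

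The targeted gene and the best known readouts of its pathway were examined first. Ctnnb1, which encodes beta-catenin (chromosome 9, 120929216 to 120960507), fell in SD at E12.5 by 0.31 on the log2 scale, from 10.80 ± 0.10 to 10.50 ± 0.15 (SD, n = 3 each; adjusted p = 0.0133). Its log2 change was -0.16 in SD at E13.5 (adjusted p = 0.205), -0.12 in SO at E12.5 (0.314) and -0.08 in SO at E13.5 (0.446). Axin2, a feedback inhibitor induced by Wnt signals (chromosome 11, 108920349 to 108950783), fell in SD by 1.03 and 1.01 at the 2 stages (adjusted p = 0.000553 and 0.000495) and rose in SO by 3.47 and 3.73 (4.27e-13 and 5.85e-14). Lef1, a transcription factor that binds beta-catenin (chromosome 3, 131110471 to 131224356), fell in SD by 2.42 and 3.79 (adjusted p = 0.00293 and 1.13e-05) and rose in SO by 3.51 and 3.95 (5.93e-06 and 4.3e-07). Nkd1, a Wnt antagonist (chromosome 8, 88521354 to 88594884), rose in SO by 2.54 and 3.53 (adjusted p = 3.07e-12 and 4.57e-15). In SD its log2 change was -0.26 and -0.35 (adjusted p = 0.365 and 0.145), and -0.30 in the mean of stages (0.0371). Foxd1, the stromal progenitor gene whose promoter drives Cre (chromosome 13, 98354242 to 98359305), fell in SO by 0.77 at E12.5 and 1.26 at E13.5 (adjusted p = 0.00149 and 1.77e-06), with SD values of -0.01 and 0.11 (0.986 and 0.825). The value of a whole gene cannot show a deleted or stabilising exon, so Ctnnb1 by itself does not check the genotype labels. Its E12.5 call in SD ended without SD replicate 2 or 3 or wild-type replicate 1 or 2 (adjusted p up to 0.122), and it overlaps Ulk4 on the other strand. The Nkd1 call in the SD mean ended without any of 10 of the 12 libraries, all but SD E12.5 replicate 1 and wild-type E13.5 replicate 1 (up to 0.0891).

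**Figure D1:**
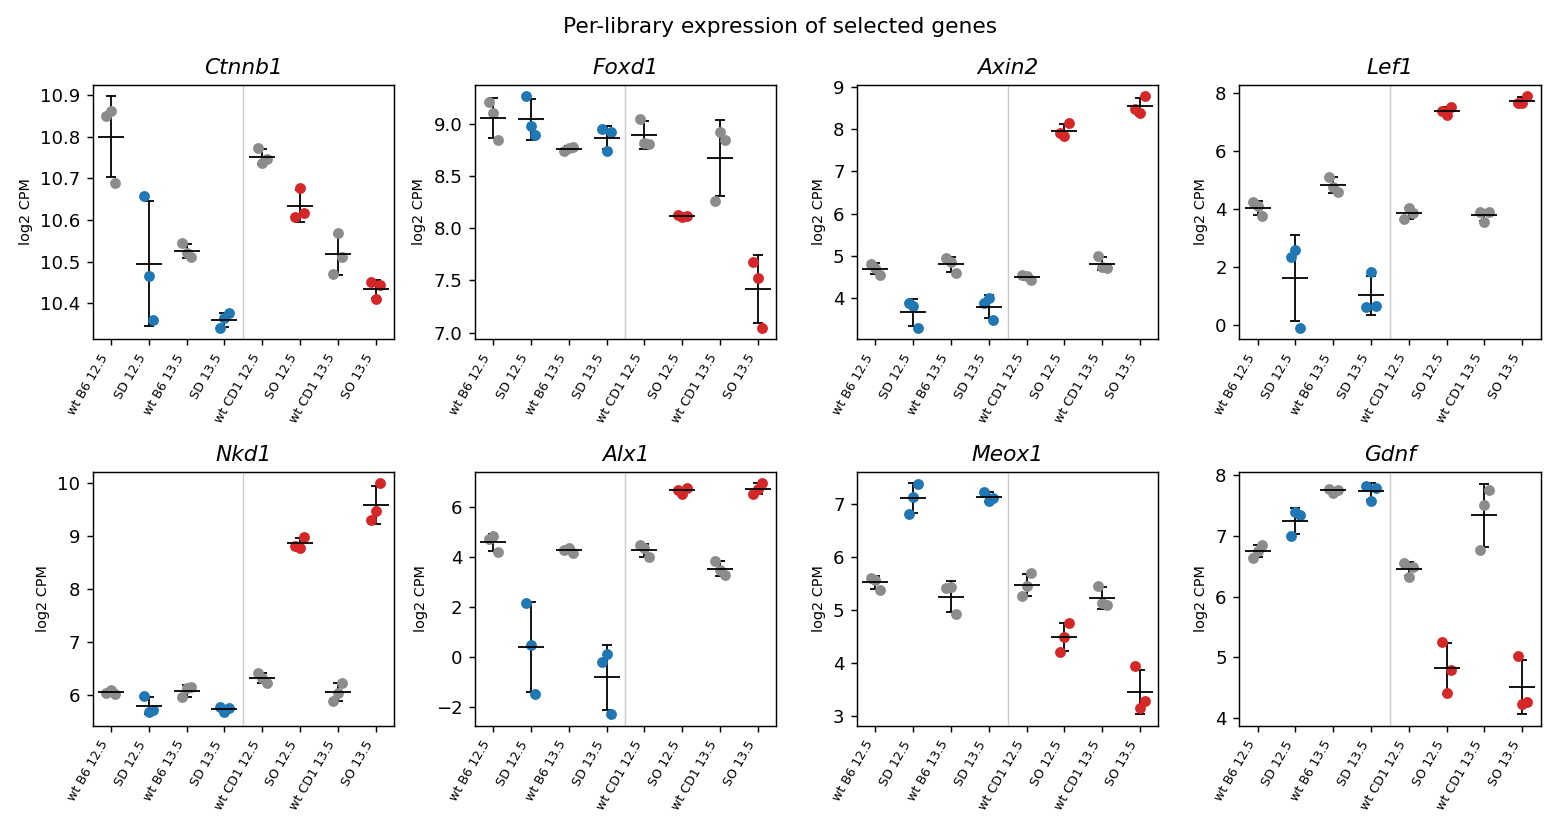
Log2 CPM of 8 genes in each library, by group, with C57BL/6 wild-type and SD on the left of each panel and CD1 wild-type and SO on the right. Dots are libraries (3 per group), long bars are group means and error bars are standard deviations. Axin2 fell in SD by 1.03 at E12.5 and rose in SO by 3.47, and Foxd1 fell in SO by 1.26 at E13.5.

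Loss of beta-catenin at E12.5 lowered Alx1, a homeobox gene on chromosome 10 (102998707 to 103030215), by 4.20 ± 0.57 (log2, SE), from 4.59 ± 0.33 to 0.40 ± 1.81 (SD, n = 3 each; adjusted p = 0.000225). It raised Ccl11, the chemokine eotaxin, by 2.85 ± 0.36 (adjusted p = 0.000117), Megf11, a transmembrane protein with EGF-like repeats, by 3.33 ± 0.50 (0.000597), and Ankrd63 by 2.95 ± 0.43 (0.000498). Further large rises were in Igfbp6, which binds insulin-like growth factors (3.88, adjusted p = 0.0205), the matrix protein gene Tnn (3.58, 0.0175) and the splicing regulator Rbm20 (3.49, 0.0235). Among the large falls, Rpl29, which encodes a ribosomal protein and is near-identical to transcripts at 35 other loci, changed by -3.30 (adjusted p = 0.00311), so that its value is uncertain. The others were the apolipoprotein gene Apoc1 (-3.88, 0.0306), the RNA-binding protein gene Rbm47 (-3.59, 0.0329), the carbonic anhydrase gene Car2 (-3.51, 0.047) and Vwf, which encodes von Willebrand factor of blood vessels (-3.26, 0.0166). In all, limma called 136 genes higher and 101 lower, of which 56 and 41 changed at least 2-fold. Camera called 13 of 28 lists at this stage, of which 0 with an estimated correlation (adjusted p = 0.077 to 0.592 with an estimated correlation). The count was 395 without SD replicate 1, 92 without SD replicate 3 (36 higher and 56 lower), 124 without wild-type replicate 1 (56 and 68) and 111 without wild-type replicate 2, so that the majority turned in the fits without SD replicate 3 or wild-type replicate 1. Calls ended for Igfbp6 and Rbm20 without SD replicate 2 or 3 or wild-type replicate 1 or 2 (adjusted p up to 0.147 and 0.136). The Tnn call ended without SD replicate 2 or 3 or wild-type replicate 1 (0.128), and that of Apoc1 without SD replicate 1 or wild-type replicate 1 or 3 (0.122). Rbm47 lost its call without SD replicate 1 or wild-type replicate 2 or 3 (0.12), Car2 without SD replicate 2 or any wild-type library (0.207) and Vwf without SD replicate 2 or wild-type replicate 2 or 3 (0.0838). Wild-type replicate 3 was also the library highest in the liver transcript Alb (log2 CPM 10.44, against -4.35 and -3 in replicates 1 and 2).

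At E13.5 the SD cells again had less Alx1, by 5.06 ± 0.57 (adjusted p = 1.22e-05), and more Tnn, by 4.20 ± 0.79 (0.00299), and Megf11, by 2.15 ± 0.50 (0.0163). Cd36, a receptor for fatty acid uptake, rose by 2.35 ± 0.46 (adjusted p = 0.00431). Further rises were in Cntnap5b, of the contactin-associated family (3.0, adjusted p = 0.000972), the actin-related gene Actr3b (2.61, 0.00353) and Olfm2, of the olfactomedin family (2.13, 0.00172). Several of the largest falls were in genes of blood vessels and blood. Aplnr, the apelin receptor of endothelial cells, fell by 4.94 ± 1.04 (adjusted p = 0.00736). The endothelial adhesion gene Esam was 36.4-fold lower in reads (counting interval 12.2 to 179, adjusted p = 0.00323) and the endothelial receptor gene Robo4 64.4-fold (11.2 to 2580, 0.00695). The immune-associated GTPase gene Gimap4 was 83.8-fold lower (14.7 to 3340, adjusted p = 0.00864) and the embryonic globin gene Hbb-bh1 154-fold (42.3 to 1280, 0.0292). In all, limma called 183 genes higher and 286 lower, of which 49 and 175 changed at least 2-fold. The majority turned with voom weights, to 120 higher and 73 lower, and with the macrophage, endothelial and erythroid list means as covariates, to 97 and 55. Of the 28 lists camera called 7, of which 0 with an estimated correlation (adjusted p = 0.0918 to 0.558 with an estimated correlation). The calls were shared with E12.5 for 63 genes that rose (1.8 expected of independent lists) and 60 that fell (2.09 expected), with 0 in opposite directions. The count was 244 without SD replicate 1, 274 without SD replicate 3, 258 without wild-type replicate 2 and 257 without wild-type replicate 3. The Megf11 call ended without SD replicate 1 or 3 or wild-type replicate 2 or 3 (adjusted p up to 0.0959), and that of Hbb-bh1 without SD replicate 1 or 3 or wild-type replicate 3 (0.201).

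Averaged over the stages, SD cells had lower levels of most called Wnt targets and of 4 of 10 medullary stroma genes. Lef1 and Nkd1 belong to both of these lists, so the lists are not separate evidence. Of 18 Wnt and beta-catenin targets, 9 fell and 2 rose (9 and 3 adjusted over the list alone), with falls in Lef1 (-3.10 ± 0.30), Axin2 (-1.02 ± 0.11), the Wnt inhibitor gene Apcdd1 (-0.99 ± 0.13) and the transcription factor gene Tcf7 (-1.55 ± 0.22). The members that rose were Dkk1, a secreted Wnt antagonist (0.96 ± 0.15), and the hyaluronan receptor gene Cd44 (0.46 ± 0.13). Camera called the list lower at adjusted p = 0.000269, and the adjusted p = 0.127 with an estimated correlation. Of 10 medullary stroma genes, 4 fell and 1 rose (4 and 1 adjusted over the list alone), namely Alx1 (-4.63 ± 0.40), Lef1, Nkd1 and Zeb2 (-0.35 ± 0.07), and Cdkn1c, a cell cycle inhibitor (0.35 ± 0.06), in the other direction. That list was lower at adjusted p = 0.0299, with adjusted p = 0.127 with an estimated correlation, and 0.0557 without SD E12.5 replicate 1. Of 16 cortical and progenitor stroma genes, 1 rose and 2 fell (5 and 2 adjusted over the list alone), and the list was not called (adjusted p = 0.52). The transcription factor gene Tcf21 fell by 1.37 ± 0.14 (adjusted p = 1.81e-06), Fat4, an atypical cadherin, by 0.44 ± 0.12 (0.0216) and the zinc finger gene Sall1 rose by 0.31 ± 0.07 (0.00319), while Fibin had 0.39 ± 0.12 (0.0556). Across genes, limma called 478 higher and 512 lower in the mean of stages, 84 and 234 of them at least 2-fold. The majority turned with a pseudocount of 1 (502 higher and 443 lower), voom weights (383 and 260), the 12 libraries of the line (461 and 403) and the macrophage, endothelial and erythroid list means as covariates (222 and 129). It also turned without the 2 libraries highest in Alb (484 and 482), and without SD E12.5 replicate 1 (556 and 508), wild-type E12.5 replicate 3 (455 and 453) or wild-type E13.5 replicate 1 (485 and 449). The Fat4 call ended without SD E12.5 replicate 3, SD E13.5 replicate 1 or 3, wild-type E12.5 replicate 2 or wild-type E13.5 replicate 1 (adjusted p up to 0.0679), and Zeb2 overlaps Zeb2os on the other strand.

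Other signalling lists moved in SD as well. Of 17 GDNF and FGF genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone), among them Etv4 (0.70 ± 0.13), Etv5 (0.56 ± 0.09, near-identical to a transcript at 1 other locus), Spry4 (0.40 ± 0.09) and Spry1 (0.23 ± 0.07), which respond to FGF signals. Camera gave adjusted p = 0.00234, and adjusted p = 0.113 with an estimated correlation. Of 14 retinoic acid genes, 5 rose and 1 fell (6 and 1 adjusted over the list alone). Cyp26b1, which degrades retinoic acid, rose by 1.38 ± 0.19, Ecm1 by 0.58 ± 0.09 and the binding protein gene Crabp1 by 0.52 ± 0.10, and Stra6, the retinol transporter gene, fell (-0.97 ± 0.13). The retinoic acid list had adjusted p = 0.00557, and adjusted p = 0.113 with an estimated correlation. Of 27 extracellular matrix genes, 4 rose and 1 fell (6 and 1 adjusted over the list alone), with Tnc (0.86 ± 0.16), Fbln5 (0.57 ± 0.12), Bgn (0.51 ± 0.11) and Fbln1 (-0.30 ± 0.06). The matrix list was higher at adjusted p = 0.0493, and adjusted p = 0.747 with an estimated correlation. The Hedgehog list was higher with 2 of 9 members called, Cdon (0.53 ± 0.13) and Boc (0.26 ± 0.08), which are Hedgehog co-receptors (6 higher adjusted over the list alone, adjusted p = 0.00295, and adjusted p = 0.25 with an estimated correlation). The receptor gene Ptch1 had 0.42 (adjusted p = 0.0771). The Hippo list had 1 member higher, Ctgf (0.69 ± 0.18), and Fat4 lower of 13 (4 and 1 adjusted over the list alone, adjusted p = 0.0493, and adjusted p = 0.555 with an estimated correlation). Cyr61 had 0.60 (adjusted p = 0.0706) and Axl 0.27 (0.079). The mitotic genes Aurka (-0.24, adjusted p = 0.0568), Bub1 (-0.19, 0.0631), Plk1 (-0.23, 0.0655) and Top2a (-0.18, 0.0877) came nearest to a call among 20 cell cycle genes. That list was lower with 0 members called over all genes and 4 lower adjusted over the list alone, at adjusted p = 0.00772, and adjusted p = 0.429 with an estimated correlation. The matrix list's adjusted p was 0.974 without SD E12.5 replicate 3, 0.414 without SD E13.5 replicate 3. It was 0.129 and 0.0558 without wild-type E12.5 replicate 1 and 2, and 0.0787 and 0.096 without wild-type E13.5 replicate 2 and 3. The Spry1 call ended without any of 9 of the 12 libraries, all but SD E12.5 replicate 1, SD E13.5 replicate 2 and wild-type E12.5 replicate 1 (adjusted p up to 0.102). That of Boc ended without any of 10, all but SD and wild-type E12.5 replicate 1 (0.105).

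Markers of other cell types also differed in SD. Of 14 macrophage and immune genes, 12 fell and 0 rose (14 and 0 adjusted over the list alone), including the mannose receptor gene Mrc1 (-2.25 ± 0.37), the chemokine receptor gene Cx3cr1 (-1.93 ± 0.35, overlapping Wdr48 on the other strand), the complement gene C1qa (-1.98 ± 0.37) and Aif1 (-2.65 ± 0.52). The list mean was 0.86 ± 0.80 in SD and 3.65 ± 0.40 in wild-type at E13.5 (SD, n = 3 each). At E12.5 it was 2.81 ± 0.64 and 3.56 ± 1.51, where the libraries overlapped (2.671, 2.247 and 3.5 in SD, 2.54, 2.842 and 5.299 in wild-type) and the highest was wild-type replicate 3, which also held the most of the liver transcript Alb. Camera called it lower in the mean of stages at adjusted p = 2.63e-14, and adjusted p = 0.127 with an estimated correlation. Of 14 endothelial genes, 7 fell and 0 rose (9 fell and 2 rose adjusted over the list alone), with the adhesion genes Pecam1 (-3.52 ± 0.68) and Esam (-3.61 ± 0.71) and the VEGF receptor genes Flt1 (-3.48 ± 0.68) and Kdr (-3.11 ± 0.66). The endothelial list had adjusted p = 0.000269, and adjusted p = 0.473 with an estimated correlation. Of 8 erythroid genes, 4 fell, among them the embryonic globin genes Hbb-bh1 (-5.37 ± 1.02), Hba-x (-4.10 ± 0.98) and Hbb-y (-3.87 ± 0.95), and the erythropoietin receptor gene Epor rose (0.75 ± 0.13). Adjusted over the list alone 5 fell and 1 rose, the list at adjusted p = 0.0182, and adjusted p = 0.429 with an estimated correlation. The nephron progenitor list was higher with 1 of 13 members called (1 adjusted over the list alone), Meox1, a homeobox gene (1.74 ± 0.13, adjusted p = 2.47e-08), at adjusted p = 0.0226, and adjusted p = 0.397 with an estimated correlation. Its next members were Osr1 (0.45, adjusted p = 0.1), Itga8 (-0.40, 0.181, overlapping another gene on the opposite strand) and Traf1 (1.49, 0.342). The cartilage list was higher with 1 of 10 called (2 adjusted over the list alone), Runx2, a transcription factor of bone (1.30 ± 0.23, overlapping Supt3 on the other strand), at adjusted p = 0.0497, and adjusted p = 0.143 with an estimated correlation. Sox5 had 0.49 (adjusted p = 0.0778), Hapln1 0.45 (0.138) and Matn4 1.71 (0.226). With the macrophage, endothelial and erythroid list means as covariates, the count of called genes in the SD mean was 351. The other 15 of 28 lists were not called in the SD mean (adjusted p from 0.095 to 0.831). Signs differed in some of them: Notch had direction up with a mean of -0.09 and a median of -0.01, axon guidance a mean of -0.05 and a median of 0.04, hypoxia a mean of 0.05 and a median of -0.10. The nephron progenitor list was not called without SD E12.5 replicate 2 (adjusted p = 0.0698) or SD E13.5 replicate 2 (0.0784).

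**Figure D2:**
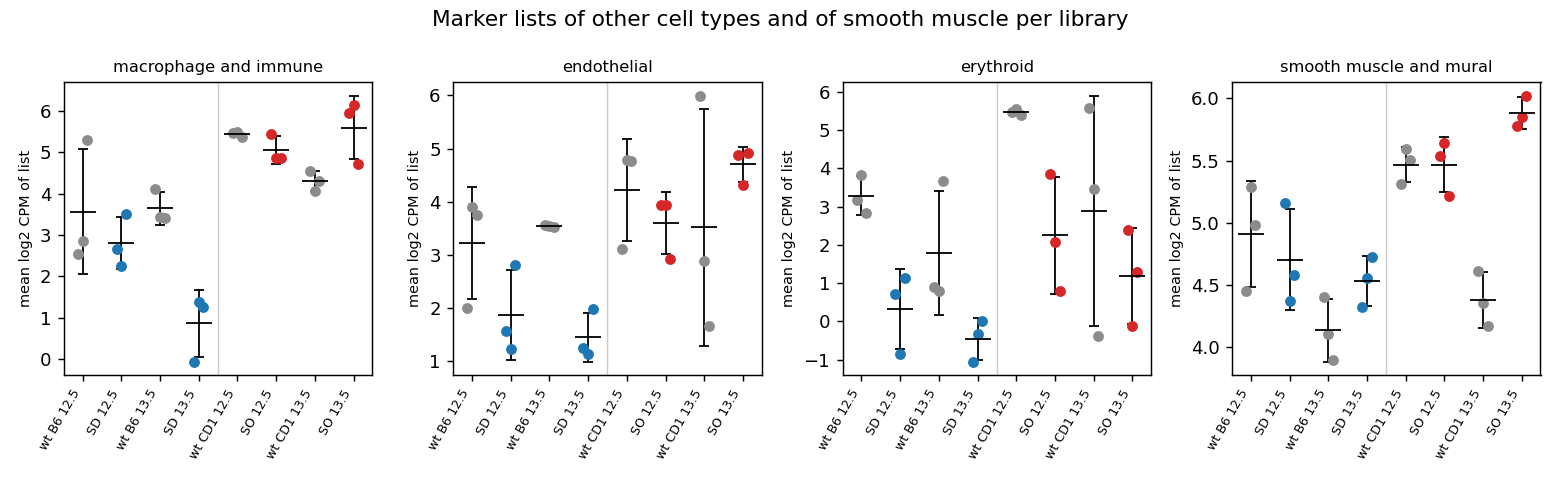
Mean log2 CPM of 4 marker lists in each library, by group. Dots are libraries (3 per group), long bars are group means and error bars are standard deviations. The macrophage mean was 2.81 in SD and 3.56 in C57BL/6 wild-type at E12.5, with overlapping libraries, and 0.86 and 3.65 at E13.5, and erythroid means in CD1 wild-type at E13.5 were widely spread, with a standard deviation of 3.01.

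Stabilised beta-catenin at E12.5 raised Notum, an enzyme that inactivates Wnt proteins (chromosome 11, 120653788 to 120661175), by 8.0 ± 1.32, from -0.68 ± 1.74 to 7.32 ± 0.14 (SD, n = 3 each; adjusted p = 0.000298). It raised Mybpc1, a myosin-binding protein, by 7.91 ± 0.76 (adjusted p = 2.09e-07), Tmem132c by 5.77 ± 0.34 (8.61e-11) and the Wnt receptor gene Fzd10 by 4.89 ± 0.56 (3.32e-06). The glutamate receptor gene Gria2 rose by 4.65 ± 0.71 (adjusted p = 0.000125) and Prdm1, a transcriptional repressor, by 4.49 ± 0.99 (0.0047). Among the largest falls were Cntnap2, of the contactin-associated family (-3.51 ± 0.61, adjusted p = 0.000521), and Tecta, which encodes a tectorin (-3.72 ± 0.84, 0.00567). Igfbp6 was 14.3-fold lower in reads (counting interval 3.74 to 122, adjusted p = 0.0136). Hbb-bh1 (-4.65, adjusted p = 0.049), Tent5c (-3.06, 0.0426) and Fmo2, a flavin-dependent monooxygenase (-2.89, 0.014), also fell. All 3 wild-type libraries here held the liver transcript Alb (log2 CPM 5.69, 5.77 and 5.45, against -3.63, -3.68 and -3.73 in SO). RNA of other tissue as a source of these falls cannot be told apart from genotype. In all, limma called 713 genes higher and 414 lower, of which 248 and 109 changed at least 2-fold. Camera called 11 of 28 lists, 4 of them also with an estimated correlation (the rest up to adjusted p = 0.431 with an estimated correlation). The count was 740 without SO replicate 2 and 720 without SO replicate 3. Calls ended for Igfbp6 without SO replicate 1 or 3 or wild-type replicate 1 or 2 (adjusted p up to 0.0807), and for Fmo2 without replicate 2 of either group (0.109). They ended for Hbb-bh1 and Tent5c without SO replicate 2 or 3 or any wild-type library (0.278 and 0.187).

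At E13.5 the SO cells had Notum higher by 9.21 ± 1.32 (adjusted p = 2.05e-05), Mybpc1 by 7.73 ± 0.76 (1.16e-07) and Tmem132c by 6.57 ± 0.34 (3.12e-12). Wif1, a secreted Wnt inhibitor, rose by 5.96 ± 0.80 (adjusted p = 9.35e-06) and the cadherin gene Cdh22 by 5.57 ± 1.04 (0.000481). The ribosomal protein gene Rpl35a was 368-fold higher in reads (counting interval 126 to 1780, adjusted p = 2.68e-13), with 3 of its reads in the wild-type libraries. Its mean was 6.61 CPM in CD1 wild-type at E12.5, 0.146 at E13.5 and 27.4 in C57BL/6 wild-type, so that this gene varied between wild-type groups as well and its value as an SO effect is uncertain. Dcx, a microtubule-associated protein gene, fell by 4.57 ± 0.83 (adjusted p = 0.000377), Igfbp6 by 4.44 ± 0.87 (0.00085) and Epn3, an epsin, by 4.33 ± 0.70 (9.6e-05). Further falls were in Xdh, which encodes xanthine dehydrogenase (-4.25, adjusted p = 0.000119), the nephron transcription factor gene Pax8 (-4.23, 0.0142) and the stress kinase gene Mapk13 (-3.86, 0.0018). A stretch of Xdh, of at most 463 nucleotides, is near-identical to transcripts at 18 other loci. Wild-type replicate 1 held much RNA of other cells, with a ureteric bud mean of 4.466 against 0.972 and 0.493 in replicates 2 and 3. In SO that mean was -0.658, 2.17 and 2.382. The neural crest and neuronal mean was 2.108, -0.178 and -0.596 in wild-type and -0.427, 0.714 and 0.948 in SO. Dcx, Epn3, Xdh and Mapk13 stayed called without any 1 library (adjusted p up to 0.0128). Other cells as a source of these falls were not tested. In all, limma called 1177 genes higher and 943 lower, of which 517 and 259 changed at least 2-fold. The majority turned under median centring, to 1050 higher and 1098 lower, and under quantile normalization, to 1130 and 1283. Of 28 lists 13 were called by camera, 8 of them also with an estimated correlation (the rest up to adjusted p = 0.503 with an estimated correlation). Between the stages, 436 genes that rose were shared (60.8 expected of independent lists) and 224 that fell (28.3 expected), with 4 and 4 in opposite directions. The Pax8 call ended without replicate 1 of either group (adjusted p up to 0.123).

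Averaged over the stages, SO cells had more of most Wnt targets and medullary stroma genes and less of most called cortical and progenitor stroma genes. Lef1 and Nkd1 count both as Wnt targets and as medullary stroma genes. Of 18 Wnt targets, 13 rose and 1 fell (14 and 1 adjusted over the list alone): Apcdd1 by 4.61 ± 0.13, Nkd2 by 3.94 ± 0.15, Axin2 by 3.60 ± 0.11 and Nkd1 by 3.03 ± 0.09, with Dkk1 lower (-0.73). Camera gave adjusted p = 2.76e-18, and adjusted p = 0.000688 with an estimated correlation. Of 10 medullary stroma genes, 8 rose and 1 fell (8 and 2 adjusted over the list alone), with the opioid precursor gene Penk up by 4.0 ± 0.44, Lef1 by 3.73 ± 0.30, Nkd1, Zeb2 by 0.78 ± 0.07 and Cdkn1c lower (-0.50). The medullary list had adjusted p = 4.25e-07, and adjusted p = 0.000904 with an estimated correlation. Of 16 cortical and progenitor stroma genes, 9 fell and 1 rose (9 and 2 adjusted over the list alone): Aldh1a2, which makes retinoic acid, by 2.21 ± 0.12, Sall1 by 1.87 ± 0.07, the guidance gene Ntn1 by 1.72 ± 0.14 and Foxd1 by 1.02 ± 0.11, with Tcf21 higher (0.81). This list was lower at adjusted p = 1.67e-07, and adjusted p = 0.0304 with an estimated correlation. In the mean of stages limma called 1411 genes higher and 1149 lower, 450 and 219 of them at least 2-fold, and under quantile normalization 1331 higher and 1506 lower.

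Lists of growth factor, retinoic acid and guidance genes were called in SO too. Of 17 GDNF and FGF genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone): Gdnf, the growth factor that draws the ureteric bud, by 2.23 ± 0.15, Etv4 by 1.19 ± 0.13 and Spry1 by 0.86 ± 0.07, with the FGF receptor gene Fgfr2 higher by 1.49 ± 0.10, although its annotated span overlaps other genes. The GDNF and FGF list had adjusted p = 6.35e-05, and adjusted p = 0.00746 with an estimated correlation. Of 14 retinoic acid genes, 6 fell and 2 rose (the same counts adjusted over the list alone), with falls in Aldh1a2, Crabp2 (-0.60 ± 0.06), Ecm1 (-0.89 ± 0.09) and Dhrs3 (-0.94 ± 0.12). Its adjusted p was 0.00366, and adjusted p = 0.0321 with an estimated correlation. Of 21 BMP and TGF-beta genes, 8 rose and 2 fell (11 and 2 adjusted over the list alone), with the BMP antagonist gene Grem1 (5.05 ± 0.52), Bmp5 (1.18 ± 0.15), Bmp4 (1.05 ± 0.15) and Tgfbi (-0.55 ± 0.06). The BMP list had adjusted p = 0.000766, and adjusted p = 0.00746 with an estimated correlation. Of 23 axon guidance genes, 14 rose and 3 fell (16 and 3 adjusted over the list alone), with the semaphorin genes Sema3a (1.84 ± 0.14, near-identical over 340 nucleotides to a transcript at 1 other locus) and Sema3c (1.79 ± 0.15), the receptor gene Robo1 (1.00 ± 0.09) and Ntn1 in the other direction. The guidance list was higher at adjusted p = 1.09e-07, and adjusted p = 0.00842 with an estimated correlation. The nephron progenitor list was not called (adjusted p = 0.148), with 2 of 13 higher and 3 lower, among them the transcription factor genes Osr1 (0.49 ± 0.16) and Meox1 (-1.38 ± 0.13), and Gdnf. The Osr1 call ended without any of 9 of the 12 libraries, all but SO and wild-type E12.5 replicate 1 and wild-type E13.5 replicate 1 (adjusted p up to 0.116).

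Some smooth muscle, cartilage and matrix genes rose in SO, and some erythroid and ribosomal protein genes fell; of these 5 lists, camera called cartilage alone also with an estimated correlation. Of 15 smooth muscle and mural genes, 9 rose and 2 fell (the same counts adjusted over the list alone): Rgs5, a pericyte gene, by 1.90 ± 0.11, smooth muscle actin Acta2 by 1.26 ± 0.19 and the transcription factor gene Tbx18 by 0.80 ± 0.11, with Cspg4 lower (-0.73 ± 0.11). The smooth muscle list had adjusted p = 0.00106, and adjusted p = 0.137 with an estimated correlation. Its means in SO and wild-type libraries overlapped at E12.5 and were apart at E13.5, where wild-type had fallen. Of 10 cartilage genes, 5 rose and 0 fell (6 and 1 adjusted over the list alone), with Runx2 (2.88 ± 0.23) and the collagen genes Col2a1 (2.41 ± 0.38), Col9a1 (1.33 ± 0.26) and Col9a2 (0.66 ± 0.15). The cartilage list had adjusted p = 0.0106, and adjusted p = 0.0321 with an estimated correlation. Of 27 extracellular matrix genes, 9 rose and 0 fell (13 and 0 adjusted over the list alone), with Vcan (0.77 ± 0.09), Fbln1 (0.47 ± 0.06), Col12a1 (0.87 ± 0.14) and Col3a1 (0.49 ± 0.09). The matrix list had adjusted p = 0.000706, and adjusted p = 0.63 with an estimated correlation. Of 8 erythroid genes, 3 fell (7 adjusted over the list alone), among them Hbb-bh1 (-3.56 ± 1.02) and Hba-x (-2.91 ± 0.98), beside Hbb-y (-2.67, adjusted p = 0.0534). The erythroid list had adjusted p = 0.002, and adjusted p = 0.254 with an estimated correlation. The CD1 wild-type libraries at E12.5 also held the liver transcript Alb, at 5.45 to 5.77 against at most -3.63 in SO at that stage. Of 24 ribosomal protein genes, 14 fell and 0 rose (15 and 0 adjusted over the list alone), with Rps2 (-1.56 ± 0.22), Rps18 (-0.31 ± 0.06), Rpl5 (-0.23 ± 0.05) and Rpl23 (-0.27 ± 0.06), which are near-identical to transcripts at 32, 6, 7 and 1 other loci and therefore uncertain. With the means of the erythroid, macrophage and endothelial lists as covariates, 1480 genes were called in the SO mean. The ribosomal list had adjusted p = 4.89e-07, and adjusted p = 0.165 with an estimated correlation. The other 16 of 28 lists were not called in the SO mean (adjusted p from 0.08 to 0.993), and early nephron had direction up with a mean of -0.72. The Hbb-bh1 call ended without SO E12.5 replicate 3 or SO E13.5 replicate 2 (adjusted p up to 0.062). The Hba-x call ended without any of 9 of the 12 libraries, all but replicate 1 of both SO groups and wild-type E13.5 replicate 3 (0.127).

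**Figure D3:**
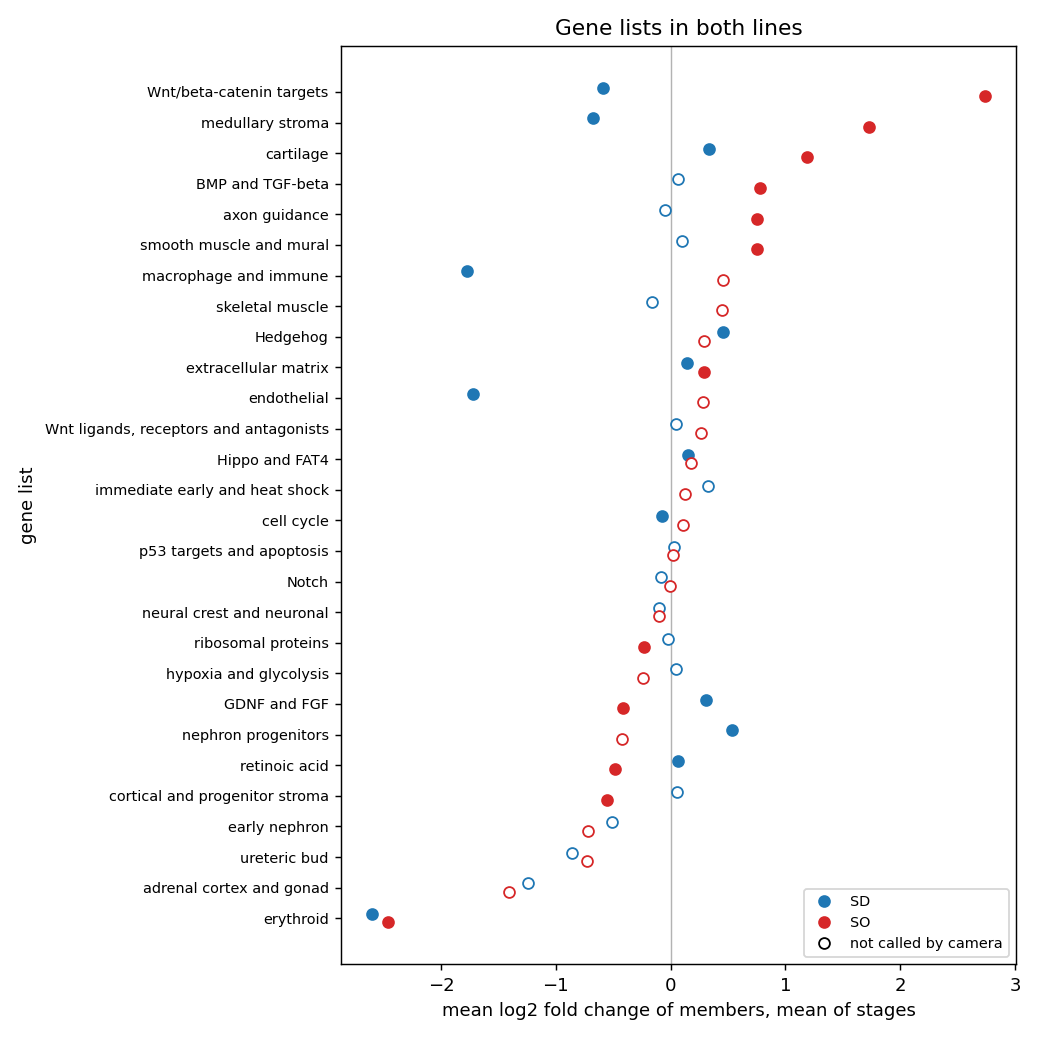
Mean log2 fold change of the tested members of each of 28 lists, in the mean of stages, for SD (blue) and SO (red). Open circles are lists that camera did not call at the preset correlation, and the line marks no change. Wnt targets were lower in SD (adjusted p = 0.000269, and adjusted p = 0.127 with an estimated correlation) and higher in SO (2.76e-18, and 0.000688 with it).

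Genes called in both lines moved in opposite directions more often than independent lists would give. There were 128 genes lower in SD and higher in SO (52.3 expected, Fisher's exact p = 1.3e-22) and 172 higher in SD and lower in SO (39.8 expected, exact p = 1.5e-67), 300 in all. With the macrophage, endothelial and erythroid list means as covariates there were 54 and 65, 119 in all. Lef1, Sp5, a transcription factor induced by Wnt signals (-2.97 ± 0.63 in SD and 4.0 ± 0.63 in SO), Alx1 (-4.63 and 2.79), the semaphorin gene Sema3e (-3.0 and 2.35), Lrriq1 (-2.25 and 3.88) and the collagen gene Col15a1 (-2.25 and 2.14) were lower in SD and higher in SO. Meox1 (1.74 and -1.38), Ankrd63 (2.30 and -1.77), Reln, which encodes the matrix protein reelin (1.47 and -1.75), the adhesion gene Chl1 (1.55 and -1.47), Igfbp7 (1.29 and -1.50, overlapping Polr2b on the other strand) and Igfbp6 (2.04 and -3.94) were higher in SD and lower in SO. In the same direction, 83 genes rose in both lines (48.9 expected, exact p = 1.07e-06) and 40 fell in both (42.6 expected, 0.744). Across all 13803 genes the mean changes of the lines had Pearson's r = -0.04 and Spearman's rho = -0.16. The SD call of Igfbp6 (adjusted p = 0.0457) ended without any of 9 of the 12 libraries, all but replicate 1 of SD E12.5, SD E13.5 replicate 2 and wild-type E12.5 replicate 3 (up to 0.141). The Col15a1 calls ended in SD without any of 10 libraries, all but SD E12.5 replicate 3 and wild-type E12.5 replicate 1 (up to 0.114), and in SO without replicate 3 of either SO group, wild-type E12.5 replicate 1 or wild-type E13.5 replicate 2 or 3 (0.0869).

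The effect of stabilised beta-catenin differed between the stages for 183 genes, 99 with a more positive and 84 with a more negative change at E13.5. These were 85 and 85 under median centring, 211 and 246 with array weights and 261 and 271 without wild-type E13.5 replicate 1. Contractile genes of smooth muscle were among the former: Myh11, smooth muscle myosin (3.32 ± 0.66, adjusted p = 0.0133), Tagln, transgelin (2.31 ± 0.43, 0.00858, overlapping Pcsk7 on the other strand), and Cnn1, calponin (3.56 ± 0.81, 0.0318). The smooth muscle list mean at E12.5 was 5.537, 5.645 and 5.218 in the SO libraries and 5.311, 5.591 and 5.501 in wild-type. At E13.5 it was 5.774, 5.849 and 6.022 in SO and 4.613, 4.353 and 4.17 in wild-type. The stage difference of this list thus came mostly from a fall in wild-type that SO lacked. Of the 15 smooth muscle genes, 5 had a more positive and 0 a more negative change (9 and 0 adjusted over the list alone; adjusted p = 3.33e-10, and adjusted p = 0.0245 with an estimated correlation). Of 28 lists tested on the stage difference, a test chosen after the data were seen, camera called 14 for SO and 2 also with an estimated correlation (the other 12 up to adjusted p = 0.47), the second being BMP and TGF-beta. That list had 2 of 21 members more positive and 0 more negative (4 and 2 adjusted over the list alone; adjusted p = 0.00466, and adjusted p = 0.0401 with an estimated correlation). The lowest p was that of the extracellular matrix list, with 4 of 27 more positive and 0 more negative (14 and 0 adjusted over the list alone; adjusted p = 9e-12, and adjusted p = 0.201 with an estimated correlation). For SD it called 4, smooth muscle with direction up and matrix, macrophage and ribosomal protein genes with direction down, of which 0 with an estimated correlation (adjusted p = 0.338 to 0.841). Rpl35a (6.15 ± 0.52, adjusted p = 5.28e-07) and the neuropeptide receptor gene Npy1r (2.60 ± 0.55, 0.0195) also had larger changes at E13.5, that of Rpl35a uncertain because its CD1 wild-type level went from 6.61 to 0.146 CPM between the stages. The differences were negative for Epn3 (-4.0 ± 0.99, adjusted p = 0.0472), Steap4, a metalloreductase (-3.26 ± 0.81, 0.0476), Polr2l, an RNA polymerase subunit near-identical to transcripts at 3 other loci (-2.84 ± 0.71, 0.0484), the glutamate receptor gene Grm3 (-2.62 ± 0.48, 0.00702) and the prostaglandin receptor gene Ptgfr (-2.43 ± 0.51, 0.0195). For SD, limma called 0 genes whose effect differed between stages, with 753 at an unadjusted p under 0.05 and 0 with voom weights, but 23 without wild-type E12.5 replicate 3, 1 without SD E12.5 replicate 2 and 1 without SD E12.5 replicate 3. The SO count was 95, 89 and 79 without SO E12.5 replicate 1, 2 and 3. It was 88, 78 and 61 without wild-type E12.5 replicate 1, 2 and 3, and 532 and 64 without wild-type E13.5 replicate 1 and 3. Calls ended for Cnn1 without SO E12.5 replicate 1 or 3, SO E13.5 replicate 3, any wild-type E12.5 library or wild-type E13.5 replicate 3 (adjusted p up to 0.0902). The Npy1r call ended without SO E12.5 replicate 3, wild-type E12.5 replicate 2 or 3 or wild-type E13.5 replicate 3 (0.0624), and that of Ptgfr without SO E12.5 replicate 2 or 3, wild-type E12.5 replicate 1 or 3 or wild-type E13.5 replicate 3 (0.0711). Those of the rest ended more widely, for Epn3 without any library but the SO E13.5 ones (0.104), for Steap4 without any but SO E13.5 replicate 1 and wild-type E13.5 replicate 1 and 2 (0.144), and for Polr2l without any but SO E13.5 replicate 3 and replicate 1 of both wild-type groups (0.129).

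Between E12.5 and E13.5, 5 of 15 smooth muscle genes in C57BL/6 and 9 in CD1 fell in wild-type stroma, and 5 of 20 cell cycle genes rose in each strain. Actg2, an actin of enteric and urinary smooth muscle, fell by 4.11 ± 0.83 in C57BL/6 and 3.84 ± 0.83 in CD1 (adjusted p = 0.00876 and 0.00832). Prelp, a matrix proteoglycan, rose by 4.66 ± 0.90 and 3.21 ± 0.90 (0.00759 and 0.0389) and Igfbp6 by 4.55 ± 0.87 and 3.26 ± 0.87 (0.00697 and 0.0306). In C57BL/6 the Hedgehog-binding gene Hhip (3.92, adjusted p = 0.0365), Rbm20 (3.25, 0.0265) and the sodium channel gene Scn7a (3.01, 0.0343) rose, and the actin gene Actc1 (-3.14, 0.031), B3gat2 (-2.95, 0.0401, overlapping Smap1 on the other strand), Mgam (-2.77, 0.0328) and Cntnap5b (-2.70, 0.0048) fell. In CD1 the collagen gene Col4a4 (3.97, adjusted p = 0.0124), the transporter gene Slco1a4 (3.17, 0.011) and the neuropeptide receptor gene Npy2r (3.12, 0.0343) rose. There the platelet genes Ppbp (-5.0, adjusted p = 0.00536) and Gp5 (-4.09, 0.0185) and the hormone gene Crh (-4.90, 0.00691) fell, and Rpl35a was 67.9-fold lower in reads (counting interval 22.9 to 332, 3.49e-09). Of 15 smooth muscle genes, 5 fell and 1 rose in C57BL/6 (8 and 2 adjusted over the list alone; adjusted p = 0.0301, and adjusted p = 0.639 with an estimated correlation). In CD1 9 fell and 0 rose (9 and 0 adjusted over the list alone; adjusted p = 3.82e-08, and adjusted p = 0.0315 with an estimated correlation). Of 20 cell cycle genes, 5 rose and 0 fell in each strain (12 and 0 adjusted over the list alone; adjusted p = 4.48e-07 and 1.86e-08, and adjusted p = 0.347 and 0.0922 with an estimated correlation). BMP and TGF-beta genes fell in CD1, 4 of 21 with 1 higher (4 and 2 adjusted over the list alone; adjusted p = 0.00225, and adjusted p = 0.0315 with an estimated correlation). Camera called 4 of 28 lists in C57BL/6, of which 0 with an estimated correlation (adjusted p = 0.347 to 0.702 with an estimated correlation), and 8 in CD1, of which 2 with it (the others up to adjusted p = 0.774). Among all genes limma called 287 higher and 259 lower in C57BL/6, and 334 and 414 in CD1. Other cell types moved beside them: the erythroid mean went from 3.29 to 1.79 in C57BL/6 and from 5.47 to 2.89 in CD1, and the liver transcript Alb in CD1 from between 5.45 and 5.77 at E12.5 to -5.06, -2.17 and 8.18 at E13.5. With the macrophage, endothelial and erythroid list means as covariates 163 and 246 genes were called in C57BL/6 and CD1, and 367 in CD1 without the 2 libraries highest in Alb. With the mean of the Y-linked genes as a covariate the counts were 312 and 443. The C57BL/6 count was 165 and 114 without E12.5 replicate 1 and 2, and 198 and 83 without E13.5 replicate 2 and 3. Its majority turned without E13.5 replicate 1 (253 higher and 301 lower), 2 (91 and 107) or 3 (38 and 45), under quantile normalization (239 and 243), with array weights (515 and 533) and with the list means as covariates (71 and 92), and was 149 and 149 without a variance trend. The CD1 count was 388, 398 and 350 without E12.5 replicate 1, 2 and 3 and 290 without E13.5 replicate 3.

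Leaving out 1 library ended several of these wild-type stage calls. In C57BL/6 the Actg2 call ended without E12.5 replicate 2 or E13.5 replicate 3 (adjusted p up to 0.0721), and those of B3gat2 and Mgam without E12.5 replicate 1 or 2 or E13.5 replicate 2 or 3 (0.165 and 0.175). Actc1 lost its call without E12.5 replicate 2 or 3 or E13.5 replicate 2 or 3 (0.138), Rbm20 without E12.5 replicate 1 or 2 or E13.5 replicate 1 or 3 (0.147), and Hhip and Scn7a without any library but E12.5 replicate 3 (0.177 and 0.168). In CD1 the Col4a4 call ended without replicate 3 of either stage (0.0844), that of Igfbp6 without any E12.5 library or E13.5 replicate 3 (0.149), and that of Prelp without any library but E12.5 replicate 1 (0.2). The Slco1a4 call ended without E12.5 replicate 1 (0.0767), that of Npy2r without any library but E12.5 replicate 2 (0.197) and that of Gp5 without any library but E13.5 replicate 1 (0.0899).

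Wild-type stroma of the C57BL/6 and CD1 backgrounds differed in 616 genes, 361 higher and 255 lower in C57BL/6. With the macrophage, endothelial and erythroid list means as covariates 41 genes were called, 32 higher and 9 lower. Without the 2 libraries highest in the liver transcript Alb, 1 in each strain, 1062 were called (500 and 562), and with the mean of the Y-linked genes as a covariate 329. Higher in C57BL/6 were Rpl35a (4.93 ± 0.26, adjusted p = 3.41e-11), Rpl29 (3.47 ± 0.41, 2.36e-05), the zinc finger gene Zfp979 (3.84 ± 0.58, 0.000573, near-identical to transcripts at 2 other loci), the meiotic cohesin gene Rec8 (2.78 ± 0.71, 0.0283) and Ctsk, which encodes cathepsin K (2.33 ± 0.41, 0.00267). Lower were the lipopolysaccharide-binding protein gene Lbp (-2.19 ± 0.42, adjusted p = 0.00446), Tagap (-1.96 ± 0.48, 0.0239, near-identical to transcripts at 2 other loci), the cadherin gene Dchs2 (-1.57 ± 0.33, 0.00849), the adaptor gene Dok2 (-1.38 ± 0.36, 0.0309, overlapping Xpo7 on the other strand) and Rprm, a cell cycle inhibitor (-1.23 ± 0.21, 0.00207). Of 14 macrophage genes, 6 were lower in C57BL/6 and 0 higher (14 and 0 adjusted over the list alone; adjusted p = 1.56e-09, and adjusted p = 0.522 with an estimated correlation). Of 20 cell cycle genes, 7 were higher and 0 lower (12 and 0 adjusted over the list alone; adjusted p = 2.91e-08, and adjusted p = 0.223 with an estimated correlation). Camera called 9 of 28 lists, of which 0 with an estimated correlation (adjusted p = 0.223 to 0.719 with an estimated correlation). The count was 233, 338 and 1007 without C57BL/6 E12.5 replicate 1, 2 and 3 (the last with 455 higher and 552 lower), 301 and 286 without C57BL/6 E13.5 replicate 2 and 3. Without the CD1 libraries it was 387, 326 and 308 for E12.5 replicate 1, 2 and 3, and 342 for E13.5 replicate 1. Calls ended for Rec8 without C57BL/6 replicate 1 or 2 of either stage, CD1 E12.5 replicate 1 or 3 or CD1 E13.5 replicate 2 (adjusted p up to 0.0721), and for Tagap without C57BL/6 replicate 2 of either stage, CD1 E12.5 replicate 1 or 3 or CD1 E13.5 replicate 1 (0.0662). The Dok2 call ended without C57BL/6 E12.5 replicate 1 or 2, C57BL/6 E13.5 replicate 2 or 3, CD1 E12.5 replicate 2 or 3 or CD1 E13.5 replicate 1 or 2 (0.1).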

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

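Tests chosen only after the result was seen were those of the macrophage transcripts, the thinning of reads and the covariate fits. The effect of stabilised beta-catenin differed between E12.5 and E13.5 in 183 genes, by a test of the difference itself. The same test gave the named genes with a larger change at E13.5, Rpl35a (6.15), Cnn1 (3.56), Myh11 (3.32), Npy1r (2.60) and Tagln (2.31). It also gave those with a more negative one, Epn3 (-4.00), Steap4 (-3.26), Polr2l (-2.84), Grm3 (-2.62) and Ptgfr (-2.43). Of 100 splits that reassigned SO and wild-type libraries within the stages, 8 gave at least 183 genes, the real one included. The highest of the others gave 2560 genes. Of the 7 others as large, 5 exchanged at least 2 more libraries at 1 stage than at the other. Such an exchange turns the shared SO effect into a stage difference, so these splits are no fair comparison for it. They cannot decide on chance, which is not excluded.

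The stage difference of SO is the first pattern weighed, since the SO E13.5 libraries were also the deepest, at 15.4 M reads against 6.43 M at E12.5. With all libraries thinned at random to 6.18 M reads, 20 times, the lowest count was 131 genes and the highest 166, all above the bound of 122 set before the thinning was run, which argues against depth as the whole cause. RNA of blood and vessel cells as the whole cause is argued against for 3 of the 5 smooth muscle genes, the fewest that the bound set beforehand asked for, which stayed called with the macrophage, endothelial and erythroid list means as covariates: Acta2 (from 2.083 ± 0.387 to 2.025 ± 0.457), Tagln (from 2.314 ± 0.431 to 2.25 ± 0.512) and Tbx18 (from 1.151 ± 0.227 to 1.316 ± 0.243). It stays open for the other 2: Myh11 went from 3.32 ± 0.66 to 2.71 ± 0.72 (adjusted p = 0.0841) and Cnn1 from 3.56 ± 0.81 to 3.35 ± 0.92 (0.0957), so those calls ended as the change shrank, by 0.608 in Myh11, and the error grew in both. A biological difference between the stages stays open as well, untested.

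Macrophage transcripts, lower in SD, are the second pattern, in cells sorted for a stromal marker, a gate that would remove macrophages; 0 of the 14 genes stand in another list. If SD libraries had merely been sorted more cleanly, markers of every other cell type would be lower alike: the mean change was -1.77 for the macrophage list and -0.28 for the epithelial lists. Their difference of -1.50 had an exact permutation p of 0.05 over 400 arrangements of 6 and 6 libraries, on the bound, so a cleaner sort and a loss of macrophages cannot be told apart. Mrc1 had 560 reads in SD and 3162 in wild-type, and the epithelial lists went both ways, nephron progenitors by 0.54, early nephron by -0.507 and ureteric bud by -0.858 (exact permutation p = 0.05, 0.345 and 0.225), with -2.60 for the erythroid and -1.72 for the endothelial list (0.005 and 0.01). Blood and vessel RNA as the whole cause of the other SD changes is argued against for these genes as a set, since with the 3 list means as covariates the changes of the 966 called genes outside these lists were a median 0.976 times those without (quartiles 0.647 and 1.2; 1.03 for rises and 0.868 for falls), and 251 of them stayed called, Lef1 (from -3.104 ± 0.299 to -3.639 ± 0.473) and Axin2 (from -1.018 ± 0.108 to -1.251 ± 0.169) among them, but it stays open for the 715 whose call ended, with a median of 0.841 times and a lower quartile of 0.493, while errors grew over the 966 by a median factor of 1.52.

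Rpl29, lower in SD in the mean of stages (-3.60, adjusted p = 5.19e-06), is the third pattern, since it was also higher in C57BL/6 than in CD1 wild-type by 3.47. DNA of another strain left beside the targeted locus would change other genes near Ctnnb1: 21 of 214 genes within 20 Mb were called against 958 of 13441 elsewhere (odds ratio 1.42, 95% interval 0.854 to 2.24, Fisher's exact p = 0.14), which leaves it open. By stage the odds ratio was 2.58 (1.15 to 5.08, 0.0116) in SD at E12.5 and 1.26 (0.562 to 2.45, 0.447) at E13.5, and in SO 0.43 (0.183 to 0.867, 0.0119) and 0.894 (0.585 to 1.32, 0.634). Reads shared with near-identical copies remain a candidate explanation, as Rpl29 has near-identical transcripts at 35 other loci, and a strain variant in any of them could move reads between loci. No biological explanation was tested.

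Splits of 3 against 3 libraries number 10, too few for a share under 0.05. The real and the highest other counts were 237 and 115 for SD at E12.5, 469 and 0 for SD at E13.5, 1127 and 2 for SO at E12.5, 2120 and 1 for SO at E13.5, 546 and 2 for stage in C57BL/6, and 748 and 87 for stage in CD1. In each of these 6, 1 of the 10 splits gave a count as large, the real one. For the means of stages, 1 of 100 splits gave a count as large, the real one, which is a share under 0.05. The counts were 990 against 373 at most for SD, 2560 against 1052 for SO and 616 against 42 for strain. This argues against a chance split, provided that the libraries are independent, which is not known. Opposed genes were 300 against 0, in splits that regrouped both lines at once. In splits of 1 line the median of the other counts was 0 for the SD and SO means. The splits of opposed genes thus test for effects in both lines, and cannot test the opposite direction. For the stage difference of SD, limma called 0 genes in the real split (753 at an unadjusted p under 0.05, and 0 with voom weights), so that 100 of 100 splits gave as many, with 373 at most.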

How the results depend on the processing

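Alternatives added after the data were seen were the covariate fits, those without the 2 libraries highest in Alb, the thinnings of reads and the list tests on the stage differences; the cause of each move below was not tested, except that fits on fewer libraries have fewer degrees of freedom and that errors with the covariates were compared. Counts of called genes stayed within 1.5 times of those reported under median centring, quantile normalization, the stricter filter and the pseudocount of 1, and the fit without a filter was identical because the filter removed no gene. Array weights gave 455 genes for SD at E12.5, 894 for SD at E13.5, 1878 for SO at E12.5, 457 for the stage difference of SO and 1048 for stage in C57BL/6. Fits on 2 groups gave 92 for SD and 1781 for SO at E12.5, 1147 for SO at E13.5 and 409 for stage in CD1, and the 12 libraries of the line 262 for stage in C57BL/6. Voom weights gave 193 for SD at E13.5 and 643 for the SD mean. Without a variance trend the counts were 76 for the stage difference of SO, 298 for stage in C57BL/6 and 407 for strain. With the blood and vessel list means as covariates they were 154 and 152 for SD at E12.5 and E13.5, 581 for SO at E12.5, 351 and 1480 for the SD and SO means, 2 for the stage difference of SD, 163 and 246 for stage in C57BL/6 and CD1, 41 for strain and 119 for opposed genes; errors grew by a median factor of 1.52 in the genes called in the SD mean and of 1.37 in those of strain, and their changes were a median 0.976 and 0.866 times those without covariates (genes outside the 3 lists). Without the 2 libraries highest in Alb they were 22 and 112 for the stage differences of SD and SO, 367 for stage in CD1 and 1062 for strain. With the Y-linked mean as a covariate they were 88 for the stage difference of SO, 312 and 443 for stage in C57BL/6 and CD1 and 329 for strain. Leaving out each library gave 92 to 395 and 244 to 370 for SD at E12.5 and E13.5, 720 to 883 and 1538 to 2286 for SO, 753 to 1064 and 2146 to 2553 for the SD and SO means, 0 to 23 and 61 to 532 for the stage differences of SD and SO, 83 to 605 and 290 to 785 for stage in C57BL/6 and CD1, 233 to 1007 for strain and 236 to 370 for opposed genes. With an estimated correlation camera called 0 lists for SD at E12.5, at E13.5 and in the mean, 4 and 8 for SO at E12.5 and E13.5, 0 and 2 for stage in C57BL/6 and CD1 and 0 for strain, and on the 12 libraries of the line 2 for stage in C57BL/6. The SD adjusted p with an estimated correlation was 0.127 for Wnt targets and for medullary stroma, 0.747 for matrix and 0.397 for nephron progenitors, and in SO 0.63 for matrix; on the 12 libraries it was 0.0658 for medullary stroma and 0.0785 for matrix in SD. Over the left-out libraries the SD list p ran from 2.82e-05 to 0.00179 for Wnt targets, 0.401 to 0.787 for cortical stroma, 0.0021 to 0.0557 for medullary stroma, 0.00173 to 0.974 for matrix and 0.00632 to 0.0784 for nephron progenitors, and in SO from 5.07e-19 to 2.91e-17, 1.75e-09 to 4.39e-07, 2.33e-07 to 3.4e-06, 8.53e-05 to 0.00373 and 0.0536 to 0.519. Of 5379 values of 233 named results, 4810 kept direction and side of the threshold, 506 lost and 48 gained the call and 15 reversed. Foxd1, not called in SD, reversed at E12.5 to 0.007 with voom weights and to 0.024, 0.064, 0.069 and 0.015 on leaving out SD replicate 2, SD replicate 3, wild-type replicate 1 and wild-type replicate 2, with a range over all 6 libraries from -0.121 to 0.069. It reversed at E13.5 to -0.126 with the covariates, and in the mean to -0.111 with them, to -0.004 without the Alb libraries, and to -0.006 and -0.004 without SD E12.5 replicate 1 and wild-type E12.5 replicate 3, with a range up to 0.089. With the covariates Ctnnb1 in SO at E13.5 went to 0.024, Hbb-bh1 to 0.056 in SO at E12.5, and Hbb-bh1, Hba-x and Hbb-y to 0.703, 0.854 and 0.723 in the SO mean, where the erythroid mean that these genes help to form was itself a covariate. A block for the replicate number gave 293, 489, 1111 and 2146 genes for SD and SO at E12.5 and E13.5 in that order of lines, and 311 opposed genes. At these depths 68.3% of simulated 2-fold changes were recovered in SD at E12.5, so smaller changes can be missed.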

Other observations

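The developmental genes and the liver and sex-linked transcripts below were chosen after their values were seen. Stabilised beta-catenin went with transcripts of several developmental genes, most of them for transcription factors, of which most had few reads in wild-type stroma. Of 12 such genes looked at, 8 passed the test as higher in SO at both stages, 2 at E12.5 alone and 2 at neither stage. In the SD mean of stages the adjusted p of the 12 ran from 0.215 to 0.955. Zic1, a zinc finger factor of neural development, had no read in CD1 wild-type and was at least 93.6-fold higher in SO at E12.5 and at least 19.6-fold at E13.5, against a floor of 3 reads over the group. The homeobox gene Irx5 was at least 109-fold higher at E12.5, and 14.6-fold higher at E13.5 (counting interval 9.14 to 25). Zic2 was higher by 4.98 and 6.11 on the log2 scale (adjusted p = 0.00388 and 0.000234), the homeobox gene Msx1 by 5.46 and 5.23 (0.00354 and 0.00272). Mab21l1 rose by 6.62 at E12.5 (adjusted p = 1.38e-05) and was 606-fold higher in reads at E13.5 (counting interval 108 to 24000), and Irx6 was 43.5-fold (14.4 to 215) and 26.1-fold (8.72 to 129) higher. Irx3 rose by 4.35 at E12.5 (adjusted p = 0.0313) and had 2.72 at E13.5 (0.156), while Msx2 had 3.30 and 2.83 (0.0756 and 0.0977). Tfap2b lay the other way, with 4 reads in SO against 23 in wild-type at E12.5 and 35 against 111 at E13.5 (adjusted p = 0.901 and 0.748). The Irx3 call at E12.5 ended without any SO library or wild-type replicate 1 (adjusted p up to 0.219). Barhl2 lost its E12.5 call without SO replicate 2 (0.0587), and at E13.5 it had adjusted p = 0.0592.

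Transcripts of liver were seen in some wild-type libraries, while Alb was at most 1.28 in the SD and SO libraries. Albumin, Alb, reached a log2 CPM of 10.44 in C57BL/6 wild-type E12.5 replicate 3, with the fetal liver gene Afp at 11.08, and 8.18 in CD1 wild-type E13.5 replicate 3, with Afp at 8.90. In the 3 CD1 wild-type E12.5 libraries Alb was 5.69, 5.77 and 5.45, and it was at most 1.93 in the others. The SO libraries at E12.5 had -3.63, -3.68 and -3.73. In that contrast liver RNA goes with genotype, and leaving out libraries cannot separate the 2. Xist, transcribed from the inactive X chromosome, was at -1.45 in SD E12.5 replicate 3, where the Y-linked gene Ddx3y was at 6.67, and between 3.99 and 10.27 in the other 23 libraries. Ddx3y was between 2.59 and 6.65 in those 23, so they held RNA of both male and female cells. That argues against a single kidney as the source of each of them, although carry-over between libraries was not tested.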
